A study of Mus musculus with 12 samples.

How the data were processed

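RNA was measured by sequencing in 12 mouse libraries that fall into 4 groups of 3. Per the labels, haematopoietic stem cells (HSC) were sorted as lineage-negative cells positive for Sca1, Kit and CD150 and negative for CD48. Committed granulocyte and macrophage precursors (preGM) were sorted as lineage-negative, Kit-positive cells negative for Sca1, CD150, CD105, CD41 and CD16/32. Cells came either from wild-type C57BL/6 mice (WT) or from a strain whose label places MLL-ENL at Col1a1 (MLL-ENL). All cells, WT included, were cultured for 48 h with doxycycline at 1 µg/ml in OptiMEM with 10% serum, SCF at 10 to 50 ng/ml, IL3 at 5 ng/ml and G-CSF at 5 ng/ml. RNA was extracted with RNeasy micro columns and amplified with a SMARTer low-input kit, per the labels. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

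Each deposited file lists exons, introns and spliced transcripts with 2 values per feature, per the file headers. The first is a raw read count that the authors did not normalize. The second is RPKM, reads scaled by feature length and library size, computed by the authors before deposit. Dividing the counts by length and RPKM, over exons with counts above 500, gave 1 library size per file. Per the submitters' processing notes, TopHat2 2.0.8, Bowtie2 2.1.0, HTSeq and edgeR were used, without a role or an order for each. The genome build is not given in the sources used here. Each file held 1244064 features of 93615 transcripts. Of these transcripts, 89664 (95.8%) matched the mouse GENCODE M21 annotation on GRCm38 by identifier, and 77052 of the matched ones (85.9%) had identical exons. Coordinates are those of GRCm38, counted from 1.

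Overlapping transcripts repeat the same reads, so gene counts were built from the deposited exon counts. For each gene, the set of non-overlapping exons with the most bases was chosen and its counts were summed. The chosen exons held 99.4% of all exon bases. Of 3951 transcripts with no identifier match, 2359 were assigned by exon overlap with 1 gene on the same strand and 1592 were left out, with 0.542% to 1.59% of the counts in a library. This gave 37086 genes. The authors' counts took no account of strand: for all 1698 tested exons lying in introns of the opposite strand, the intron's count was at least that of the exon. Reads from overlapping or antisense genes can therefore not be told apart, and 3811 genes shared at least 10% of their exon bases with another gene. Members of families with near-identical copies (Bcl2a1, H2, Ear and Hist1 genes) and pseudogenes such as Eif5al3-ps and Rps15a-ps8 are uncertain because reads of similar sequence can be assigned to the wrong copy.

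Total gene counts per library were 14518798 to 18145089 in WT HSC, 18966266 to 23436018 in MLL-ENL HSC, 34708594 to 44459882 in WT preGM and 38438059 to 50300532 in MLL-ENL preGM. A count of 3 in a library corresponded, as a group mean, to 0.163, 0.107, 0.105 and 0.0790 CPM (counts scaled to 1 megacount per library) in these groups. That value was used as the floor for a group in which a gene had no counts. Floors and intervals cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

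Genes were tested with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3 on the gene counts, with all 12 libraries in 1 fit, a mean per group, TMM scaling and robust dispersion estimates. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15), which left 15662 genes. The common biological coefficient of variation was 0.320. All 5 comparisons are two-sided, and all adjusted p-values of genes are Benjamini-Hochberg values over the 15662 genes, with a threshold of 0.05. The comparisons were MLL-ENL against WT in HSC, the same in preGM, the difference of these responses (interaction, preGM response minus HSC response), preGM against HSC in WT, and preGM against HSC with MLL-ENL. No MLL-ENL library lacked doxycycline, so the effect of the fusion cannot be told apart from other differences between the strains. Changes with, and responses to, MLL-ENL are meant in this sense throughout. Log2 fold changes are those of the edgeR fit, with its default prior count. Their standard errors (SE) were back-calculated as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. A prior count of 2 was used for log2 CPM values (principal components, correlations between libraries and list tests), not for the fold changes. Levels are CPM after TMM scaling, as mean ± standard deviation (SD) with n = 3. With 3 libraries against 3, an exact permutation test of a single value has 10 splits and a smallest two-sided p of 0.1.

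Gene lists were fixed from general knowledge: 16 were tested and 2 others, of sex-linked genes and of genes that follow RNA quality, served as checks. List tests used camera (limma 3.58.1) with a preset correlation between genes of 0.01, and Benjamini-Hochberg adjustment over the 16 lists of a comparison. The same test with an estimated correlation was run beside it. Counts "adjusted over the list alone" use Benjamini-Hochberg over the members of 1 list. Over the 5 comparisons, 50 counts of list members called in 1 direction were 0 by the edgeR test. Of these, 31 were also 0 at an unadjusted p under 0.05 (at most 8 members otherwise), 38 with DESeq2 (at most 3) and 43 with limma (at most 4). Further lists for the closing tests (major histocompatibility complex class II, other dendritic cell, macrophage, primary granule and secondary granule genes) were written after the first results had been seen.

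Genes are named by a fixed rule. Hoxa9, Meis1, Mllt1, Kmt2a and Col1a1 are reported in every comparison. For each of the MLL-ENL comparisons, the 10 largest increases and the 10 largest decreases were eligible. For the interaction and for preGM against HSC in WT, the 5 largest in each direction were eligible. These had to pass adjusted p 0.05, have groups that did not overlap (for the interaction, in at least 1 cell type) and reach a mean of 5 RPKM in their highest group. From each list, up to 4 members with the smallest p were eligible. Predicted genes and small RNAs known only by a number were counted and not named. Where fewer than 5 genes passed in a direction, those with the smallest unadjusted p were to be added, which was not needed. Some genes given by the rule are not reported here. Genes outside this rule are said to have been chosen after their values were seen.

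The comparisons, tests, gene lists, naming rule and most alternatives were chosen before the data were examined. The alternatives were DESeq2 1.42.0 (Wald test), DESeq2-type size factors in edgeR, library size without TMM, no filter, a filter of 5 CPM in at least 3 libraries, dispersion without the robust option, only the groups compared, the replicate number as a block, limma on log2(RPKM + 1) and on log2(RPKM + 0.1) with at least 1 RPKM in at least 3 libraries, and leaving out each library in turn. Log2 changes from the RPKM alternatives are on the log2(RPKM + pseudocount) scale, where the pseudocount understates the ratio of low RPKM values, and they can lie above or below those of edgeR. Chosen after seeing the data were counts of the longest transcript of each gene, leaving out mitochondrial and ribosomal-RNA-like features, and leaving out WT preGM replicate 2 and MLL-ENL preGM replicate 1 together.

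The gene test was checked on simulated counts of the 15662 genes with 200 of them changed by 2-fold or 4-fold, and recovery was counted over those that passed the filter. Of the genes changed 4-fold, it recovered 68.4% of 98 in the HSC comparison, 68.4% of 98 in preGM, 33.0% of 97 in the interaction and 71.4% of 98 for preGM against HSC in WT. Of those changed 2-fold, it recovered 4.12% of 97, 5.05% of 99, 0% of 100 and 12.1% of 99. False calls were 5.33%, 5.26%, 8.57% and 6.82% of the genes called. For lists, 100 simulated lists of 20 genes with a log2 shift of 1 were called in 100% of cases, and unshifted lists in 5% with the preset and 2% with the estimated correlation. Genes were simulated as independent, so these rates do not cover lists whose members correlate. The estimated correlation of the real lists reached 0.242, for the cytokine receptor genes.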

Results

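RNA was profiled in sorted HSC and preGM from WT and MLL-ENL mice after 48 h of culture with doxycycline, in 12 libraries with 3 per group. MLL-ENL is a leukaemia fusion of the histone methyltransferase MLL (Kmt2a) with ENL (Mllt1), a reader of acetylated histones. Gene counts per library, in megacounts, averaged 16.0 ± 1.92 in WT HSC (SD, n = 3), 21.2 ± 2.24 in MLL-ENL HSC, 41.2 ± 5.62 in WT preGM and 43.9 ± 5.98 in MLL-ENL preGM. HSC libraries were thus shallower than preGM libraries, and between 16567 and 20159 genes had at least 1 count in a library. Mitochondrial genes took 5.63 ± 0.266%, 6.46 ± 0.215%, 3.34 ± 0.700% and 2.51 ± 0.650% of the counts in the same order (SD, n = 3). Introns that overlap no exon had 3.98 ± 0.197, 5.46 ± 0.592, 1.68 ± 0.414 and 2.27 ± 1.10 counts per 100 gene counts (SD, n = 3). Xist, the RNA that coats an inactive X chromosome, lay between 128 and 530 CPM of gene counts in all 12 libraries. Of the Y-linked genes, Ddx3y and Kdm5d had no counts in any library, while Eif2s3y reached at most 0.0689 and Uty 0.896 CPM.

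The first principal component, with 58.4% of the variance, separated HSC from preGM, and the second held 11.01%. On the second component, WT preGM replicate 2 lay at 60.1, against 10.7 and 5.38 for the other WT preGM libraries. MLL-ENL preGM replicate 1 lay at -75.1, against -23.7 and -25.6 for the other MLL-ENL preGM libraries. Meis1 reached 185 CPM in MLL-ENL preGM replicate 1 and 57.7 and 56.2 CPM in the other libraries of that group. In WT preGM replicate 2, ribosomal-RNA-like features took 4.53% of the counts, and in the other 11 libraries at most 1.96%. MLL-ENL preGM replicate 1 had 3.54 intron counts per 100 gene counts, against 1.76 and 1.52 in replicates 2 and 3. No libraries of a group agreed within sampling noise.

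**Figure D1:**
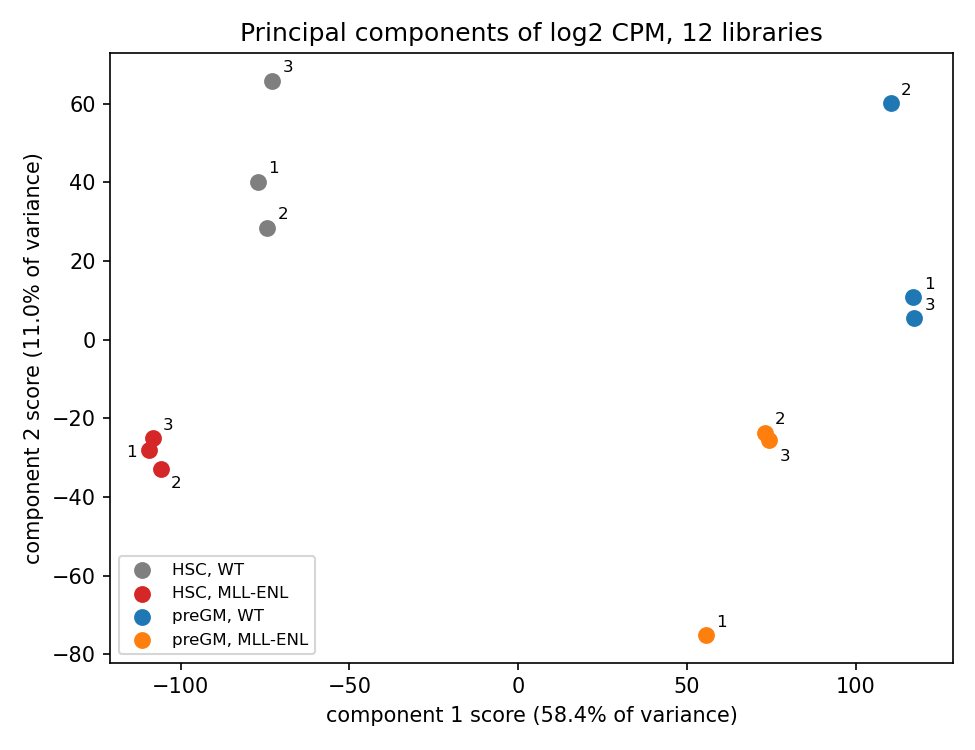
Principal components 1 and 2 of log2 CPM in the 12 libraries, with each axis giving its share of the variance and each point 1 library coloured by group. HSC and preGM part along component 1 (58.4%), and WT preGM replicate 2 and MLL-ENL preGM replicate 1 lie at 60.1 and -75.1 on component 2 (11.01%).

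The fusion was first looked for through its partner genes. Kmt2a (chromosome 9, 44803355 to 44881296) had 74.7 ± 3.67 CPM in WT HSC and 96.2 ± 7.88 CPM in MLL-ENL HSC (SD, n = 3), and 22.1 ± 5.59 and 35.1 ± 4.36 CPM in preGM. Its log2 changes with MLL-ENL of 0.36 ± 0.22 in HSC and 0.67 ± 0.22 in preGM (SE) did not pass the threshold (adjusted p = 0.407 and 0.0886). Mllt1 (chromosome 17, 56892611 to 56935415) had log2 changes of -0.48 ± 0.22 and 0.33 ± 0.22 (adjusted p = 0.258 and 0.376). The interaction passed for neither gene, with log2 values of 0.31 ± 0.31 for Kmt2a and 0.80 ± 0.31 for Mllt1 (adjusted p = 0.696 and 0.196). Col1a1, the collagen locus named in the strain label (chromosome 11, 94936224 to 94953042), had 0 to 23 counts in a library and was too low to test. Counts do not separate transcripts of the transgene from those of the endogenous genes.

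Which genes differ with MLL-ENL in stem cells was asked by comparing MLL-ENL with WT HSC. In MLL-ENL HSC, the haematopoietic transcription factor genes Mecom (chromosome 3, 29951296 to 30548008) and Pbx3 (chromosome 2, 34171457 to 34373142) rose. Mecom went from 40.1 ± 5.11 to 109 ± 8.73 CPM (SD, n = 3; log2 change 1.45 ± 0.24 SE, adjusted p = 0.00247) and Pbx3 from 7.68 ± 1.33 to 32.7 ± 4.25 CPM (2.09 ± 0.26, adjusted p = 0.00036), the latter lost with the longest transcript (adjusted p = 0.122). Cd48, which encodes the surface protein whose absence defined the HSC gate (chromosome 1, 171682009 to 171705258), fell from 111 ± 21.2 to 5.67 ± 1.29 CPM, a log2 change of -4.29 ± 0.36 (adjusted p = 1.24e-05). Sult1a1, a sulfotransferase gene enriched in stem cells (chromosome 7, 126672865 to 126676432), rose from 5.21 ± 2.84 to 70.0 ± 8.96 CPM, a log2 change of 3.74 ± 0.41 (adjusted p = 0.000125). The receptor tyrosine kinase gene Flt3 (chromosome 5, 147330741 to 147400489) fell from 14.4 ± 1.28 to 4.37 ± 1.17 CPM, a log2 change of -1.72 ± 0.31 (adjusted p = 0.00498), a call lost with limma (0.0661 and 0.0686).

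Among the 21 tested MLL fusion target genes, 3 rose and 1 fell in HSC, against 7 and 2 adjusted over the list alone. Hoxa10 was the other member that rose (1.20 ± 0.28, adjusted p = 0.0231). Its call was lost without WT HSC replicate 2 or 3, or without MLL-ENL HSC replicate 1, 2 or 3 (adjusted p = 0.0833, 0.0789, 0.0584, 0.0784 and 0.0888), and with limma on log2(RPKM + 0.1) (0.0693). Hoxa9, a homeobox gene upregulated in MLL leukaemia (chromosome 6, 52223100 to 52231089), had 27.8 ± 5.36 CPM in WT and 47.6 ± 3.66 CPM in MLL-ENL HSC (log2 change 0.77 ± 0.21, adjusted p = 0.0534). Without WT preGM replicate 2 or MLL-ENL preGM replicate 1 its adjusted p was 0.0279 or 0.0162, within a range of 0.00242 to 0.185 over all 25 alternative settings, 7 of which called it. Its cofactor gene Meis1 (chromosome 11, 18879817 to 19018985) had 137 ± 2.66 and 208 ± 7.16 CPM (0.60 ± 0.36, adjusted p = 0.389), and passed without MLL-ENL preGM replicate 1 (adjusted p = 0.0233, in a range of 0.000438 to 0.573 over its settings). The list was shifted upwards by camera (adjusted p = 0.0167, and adjusted p = 0.155 with an estimated correlation). That call was lost without WT HSC replicate 2 (adjusted p = 0.0737) or MLL-ENL HSC replicate 3 (adjusted p = 0.0576).

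Of 25 stem cell genes, 6 rose and 1 fell in HSC (11 and 1 adjusted over the list alone). Besides Sult1a1 and Mecom, these included Procr, the endothelial protein C receptor gene (1.68 ± 0.26), and Hoxb5, a homeobox gene (2.09 ± 0.41). The list test gave adjusted p = 0.00492, and adjusted p = 0.105 with an estimated correlation. Immediate early and stress genes rose in 5 of 12 cases and fell in 0 (6 and 0 adjusted over the list alone). Egr1, an early growth response factor gene (chromosome 18, 34859823 to 34864984), went from 12.1 ± 1.03 to 70.8 ± 13.8 CPM, with a log2 change of 2.54 ± 0.27. Fos (3.07 ± 0.55), Junb (1.86 ± 0.36) and Trib3 (2.76 ± 0.45) rose with it, and the list passed with both the preset and the estimated correlation (adjusted p = 5.41e-06, and adjusted p = 0.0063 with an estimated correlation). MYC and ribosome biogenesis genes moved the other way, with 3 of 17 lower and 0 higher (7 and 0 adjusted over the list alone; adjusted p = 5.41e-06, and adjusted p = 0.0063 with an estimated correlation). The 3 that fell were Srm, a spermidine synthase gene (-1.35 ± 0.31), Ncl, the nucleolin gene (-1.01 ± 0.26), and Rrs1 (-1.10 ± 0.30). Srm was lost without WT HSC replicate 1 or 3 or any MLL-ENL HSC library (adjusted p = 0.0534 to 0.105). Ncl and Rrs1 were lost without any 1 of the 6 HSC libraries (adjusted p = 0.0967 to 0.192 and 0.0833 to 0.206) or without WT preGM replicate 1 or 3 or MLL-ENL preGM replicate 3 (adjusted p = 0.0508 to 0.0635 and 0.0583 to 0.0626). Rrs1 was also lost without MLL-ENL preGM replicate 2 (adjusted p = 0.0526), with library size alone (0.0616), limma on log2(RPKM + 0.1) (0.0543) and the longest transcript (0.0519), and Ncl without a filter (0.0882).

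Of 27 proliferation genes, 0 rose and 0 fell in HSC by the edgeR test over all genes or adjusted over the list alone, while 0 higher and 7 lower had an unadjusted p under 0.05. DESeq2 called 0 higher and 1 lower, and limma 0. Ccna2 (-0.78 ± 0.23), Cenpe (-0.66 ± 0.26), Mki67 (-0.59 ± 0.25) and Pcna (-0.66 ± 0.28) were nearest to the threshold (adjusted p = 0.0742 to 0.210). As a set the list was shifted downwards (camera adjusted p = 6.52e-05, and adjusted p = 0.105 with an estimated correlation). Cell cycle inhibitor genes had 2 of 8 higher and 0 lower (4 and 0 adjusted over the list alone; adjusted p = 0.0247, and adjusted p = 0.155 with an estimated correlation). These were Rb1, the retinoblastoma gene, and Cdkn2c, a CDK4 and CDK6 inhibitor gene, with log2 changes of 1.05 ± 0.22 and 1.43 ± 0.33. Rb1 was lost without WT HSC replicate 1 (adjusted p = 0.0619) or MLL-ENL HSC replicate 1 (adjusted p = 0.0617), and with the longest transcript (adjusted p = 0.310). Cdkn2c was lost without WT HSC replicate 1 or 2 or MLL-ENL HSC replicate 1 or 3 (adjusted p = 0.0582, 0.0934, 0.0806 and 0.0909). The list itself was lost without WT HSC replicate 1 or 2 or MLL-ENL HSC replicate 3 (adjusted p = 0.0522, 0.0761 and 0.0529). Among 19 p53 target genes, Btg2, an antiproliferative gene, was the 1 that rose (1.43 ± 0.22), with 0 lower (3 and 0 adjusted over the list alone; adjusted p = 0.0247, and adjusted p = 0.161 with an estimated correlation). The p53 list was lost without WT HSC replicate 1 or 2 or MLL-ENL HSC replicate 1 (adjusted p = 0.154, 0.0855 and 0.056), and without both libraries that stood apart (0.0693). Mitochondrial mt-Co1, a gene of the RNA quality list, was also higher (1.22 ± 0.28, adjusted p = 0.0214), and this was lost without any 1 of the 6 HSC libraries (adjusted p = 0.0509 to 0.111).

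Markers of other cell types moved in both directions in HSC. Pf4, a platelet chemokine gene, fell from 481 ± 74.9 to 47.0 ± 19.0 CPM (-3.35 ± 0.56) and the globin gene Hbb-bt fell (-2.25 ± 0.42), while Apoe, which encodes a lipid transport protein, rose (2.08 ± 0.34). Of 21 megakaryocyte and erythroid genes, 1 rose and 4 fell (1 and 4 adjusted over the list alone; adjusted p = 0.243). Of 4 tested stromal and endothelial genes, 2 rose and 0 fell (3 and 0 adjusted over the list alone; adjusted p = 0.00229, and adjusted p = 0.0433 with an estimated correlation). Col1a2, a collagen gene, went from 0.991 ± 0.518 to 6.75 ± 2.13 CPM (2.75 ± 0.49). The stromal list was lost without WT HSC replicate 3 (adjusted p = 0.135), MLL-ENL HSC replicate 3 (0.0535) or both libraries that stood apart (0.104). Interferon response genes had 2 of 18 higher and 0 lower (4 and 0 adjusted over the list alone; adjusted p = 0.0167, and adjusted p = 0.0733 with an estimated correlation), with Isg15, a ubiquitin-like modifier gene, at 2.01 ± 0.39. That list was lost without WT HSC replicate 2 (adjusted p = 0.0737) or MLL-ENL HSC replicate 2 (adjusted p = 0.055). Mast cell, basophil and eosinophil genes had 0 of 11 higher and 1 lower, Fcer1a (-2.95 ± 0.40), which encodes a chain of the IgE receptor (0 and 1 adjusted over the list alone; adjusted p = 0.0428, and adjusted p = 0.155 with an estimated correlation). This list was lost without WT HSC replicate 2 or 3, MLL-ENL HSC replicate 2 or 3, or MLL-ENL preGM replicate 1 (adjusted p = 0.0761, 0.0867, 0.102, 0.07 and 0.0781), and without both libraries that stood apart (0.148). Dntt, the lymphoid DNA polymerase gene, was at least 31.7-fold lower in MLL-ENL HSC, where it had no counts, than in WT HSC (3.38 ± 0.943 CPM).

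The granulocyte and monocyte list did not pass in HSC (1 of 30 higher, 2 lower; adjusted p = 0.215), although without WT HSC replicate 1 it did (adjusted p = 0.0339). The MLL and elongation complex (1 of 14 higher, 0 lower), lymphoid (0 of 8 higher, 1 lower), BCL2 family (1 of 14 higher, 0 lower) and cytokine receptor lists (1 of 13 higher, 1 lower) did not pass either (adjusted p = 0.871, 0.605, 0.112 and 1.00). Adjusted over each list alone, these 5 lists had 2, 1, 0, 1 and 1 members higher and 3, 2, 1, 0 and 2 lower. The largest increases in HSC under the naming rule included Fbp1, the gluconeogenic enzyme gene, from 5.00 ± 1.33 to 85.4 ± 4.21 CPM (4.10 ± 0.41), Aldh1a1, a retinaldehyde dehydrogenase gene (3.28 ± 0.29), the lectin gene Clec1a (3.28 ± 0.36) and Tnfrsf14 (3.36 ± 0.49). Those of Eif5al3-ps (5.76 ± 0.41), Rps15a-ps8 (5.63 ± 0.53) and AA465934 (5.37 ± 0.44) were larger still. The first 2 are pseudogenes, so reads from their parent genes may be counted with them. Large decreases were seen for F2rl2 (-3.57 ± 0.51), the aspartic protease gene Ctse (-3.41 ± 0.40), the histone gene Hist1h1b (-3.12 ± 0.46), Tespa1 (-3.01 ± 0.38) and Plac8 (-2.86 ± 0.40).

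In total, 500 genes rose and 146 fell in HSC of 15662 tested (edgeR quasi-likelihood test), so that 77.4% of the calls were increases, and 603 of the 646 exceeded 2-fold. Intron counts differed with the genotype too, at 3.76 to 4.13 per 100 gene counts in the WT HSC libraries and 4.84 to 6.01 in the MLL-ENL HSC libraries, as did the mitochondrial share (5.40 to 5.92% and 6.33 to 6.71%). The groups did not overlap for 34.8% of genes, where chance gives 10%. The share of increases was 88.0% when libraries were scaled by size alone, 86.6% and 87.7% with limma on RPKM, 65.8% with DESeq2 and 50.8% when only the HSC groups were fitted. Without both libraries that stood apart, 3362 genes were called, 48.1% of them higher, and without MLL-ENL preGM replicate 1 the share was 62.9%. The number called was 390 and 410 without WT HSC replicate 1 and 2, 319, 312 and 329 without MLL-ENL HSC replicate 1, 2 and 3, 972 without WT preGM replicate 2 and 1281 without MLL-ENL preGM replicate 1.

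The same comparison in preGM asked what differs with MLL-ENL in committed precursors. MLL-ENL preGM had more RNA of the MLL target genes Meis1, Hoxa9, Hoxa10 and Mecom, and far less of the granulocyte genes S100a8, S100a9, Ngp, Camp and Ltf. Meis1 rose from 9.41 ± 0.709 to 99.6 ± 73.8 CPM (SD, n = 3), a log2 change of 3.40 ± 0.39 (SE, adjusted p = 6.58e-05), with 185 CPM in the library that stood apart. Hoxa9 rose from 9.33 ± 0.692 to 39.4 ± 5.14 CPM (2.08 ± 0.22, adjusted p = 2.83e-05). S100a8, which encodes a calcium-binding protein abundant in neutrophils (chromosome 3, 90668978 to 90670035), fell from 2665 ± 863 to 8.72 ± 3.98 CPM (-8.26 ± 0.51, adjusted p = 6.36e-08). Elane, the neutrophil elastase gene (chromosome 10, 79886247 to 79888215), fell from 11933 ± 1853 to 2275 ± 517 CPM (-2.39 ± 0.35, adjusted p = 0.000455).

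Of the 21 MLL fusion target genes, 14 rose and 0 fell in preGM (17 and 0 adjusted over the list alone; camera adjusted p = 2.03e-16, and adjusted p = 0.00445 with an estimated correlation). Hoxa10 (chromosome 6, 52231197 to 52240854) showed the largest change among the named members, from 0.370 ± 0.190 to 8.64 ± 1.52 CPM (4.59 ± 0.35), followed by Mecom, from 0.540 ± 0.129 to 6.93 ± 1.76 CPM (3.70 ± 0.29). Hoxa7 rose as well (2.68 ± 0.25), with 20% of its exon bases shared with another gene. Flt3 rose from 9.19 ± 0.351 to 25.3 ± 11.7 CPM (1.46 ± 0.30) and Bcl2, a survival gene, from 22.1 ± 0.843 to 42.7 ± 4.22 CPM (0.95 ± 0.21, adjusted p = 0.00936). The Bcl2 call was lost without WT preGM replicate 1 (adjusted p = 0.0558) and when only the preGM groups were fitted (adjusted p = 0.0607). Of 14 MLL and elongation complex genes, 0 rose and 0 fell by the edgeR test over all genes or adjusted over the list alone (camera adjusted p = 0.523), 3 were higher at an unadjusted p under 0.05, and DESeq2 and limma each called 1 higher. Stem cell genes rose in 13 of 25 cases and fell in 1 (14 and 1 adjusted over the list alone; adjusted p = 2.40e-08, and adjusted p = 0.00739 with an estimated correlation). Emcn, the endomucin gene (2.95 ± 0.39), was among those higher. Ly6a, which encodes the Sca1 antigen absent from the preGM gate, was the member that fell (-1.81 ± 0.25).

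Granulocyte and monocyte genes fell in 19 of 30 cases and rose in 1 (3 higher and 22 lower adjusted over the list alone; adjusted p = 7.26e-18, and adjusted p = 0.00475 with an estimated correlation). S100a9, the partner of S100a8 (chromosome 3, 90692632 to 90695721), fell from 872 ± 245 to 2.08 ± 0.948 CPM (-8.72 ± 0.46). The neutrophil granule gene Ngp went from 551 ± 152 to 1.72 ± 0.736 CPM (-8.34 ± 0.44), the cathelicidin gene Camp changed by -8.61 ± 0.46 and the lactoferrin gene Ltf by -7.83 ± 0.58. Mpo, the myeloperoxidase gene, did not pass, with 5256 ± 2613 CPM in WT and 7961 ± 3636 CPM in MLL-ENL preGM (0.60 ± 0.43, adjusted p = 0.413). Elane, which the naming rule gives only between the cell types, and Mpo were chosen for preGM after their values were seen. Mast cell, basophil and eosinophil genes fell in 6 of 11 cases and rose in 0 (1 higher and 7 lower adjusted over the list alone; adjusted p = 2.57e-07, and adjusted p = 0.00701 with an estimated correlation). The basophil protease genes Prss34 and Mcpt8 went from 231 ± 176 to 1.43 ± 0.795 CPM (-7.35 ± 0.63) and from 1213 ± 423 to 68.9 ± 31.4 CPM (-4.14 ± 0.46). Prg2, the eosinophil major basic protein gene, changed by -9.36 ± 1.02 and had 7.41, 179 and 78.4 CPM in WT preGM replicates 1, 2 and 3. WT preGM replicate 2, which stood apart, thus had the highest level of this eosinophil gene.

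BCL2 family genes rose in 2 of 14 cases and fell in 4 in preGM (2 and 5 adjusted over the list alone; adjusted p = 0.0257, and adjusted p = 0.0721 with an estimated correlation). Bcl2a1a (-4.23 ± 0.66) and Bcl2a1d (-3.08 ± 0.60) are near-identical copies, so their separate values are uncertain, and the latter was lost without both libraries that stood apart (adjusted p = 0.0912). The list call was lost without MLL-ENL preGM replicate 1 (adjusted p = 0.0572) or both libraries that stood apart (0.0982). Immediate early and stress genes had 1 of 12 higher and 1 lower (1 and 1 adjusted over the list alone; adjusted p = 0.0316, and adjusted p = 0.0779 with an estimated correlation). Fos fell (-2.26 ± 0.51) and Egr1 rose from 1.24 ± 0.358 to 2.92 ± 0.787 CPM (1.26 ± 0.29, adjusted p = 0.0132). Egr1 was lost without WT preGM replicate 1 or 3 (adjusted p = 0.0887 and 0.0534), with limma on log2(RPKM + 1) (0.117) and with only the preGM groups (0.083), and Fos with limma (0.191 and 0.165). The stress list was lost without WT preGM replicate 2 (adjusted p = 0.0765), MLL-ENL preGM replicate 1 (0.0616) or both (0.134). The remaining 9 lists did not pass in preGM. These were megakaryocyte and erythroid (3 of 21 higher, 4 lower; adjusted p = 0.845), lymphoid (2 of 8 higher, 1 lower; 0.845), proliferation (1 of 27 higher, 0 lower; 0.449), cell cycle inhibitor (1 of 8 higher, 1 lower; 0.744) and p53 target genes (0 of 19 higher, 2 lower; 0.0872). Interferon response (1 of 18 higher, 1 lower), MYC and ribosome biogenesis (0 of 17 higher or lower), cytokine receptor (1 of 13 higher, 2 lower) and stromal genes (2 of 4 higher, 0 lower) gave camera adjusted p = 0.260, 0.564, 0.800 and 0.138. Adjusted over each list alone, these 9 lists had 6, 2, 0, 1, 0, 5, 2, 4 and 2 members higher and 6, 1, 0, 1, 3, 2, 0, 4 and 0 lower. Of the MYC genes, 5 were higher and 1 lower at an unadjusted p under 0.05 with edgeR, while DESeq2 called 2 higher and limma 0. Without MLL-ENL preGM replicate 1 the p53 list passed (adjusted p = 0.0321).

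Outside the lists, the costimulatory receptor gene Cd27 rose in preGM from 9.64 ± 2.54 to 92.7 ± 25.9 CPM (3.26 ± 0.29), Myct1 from 2.88 ± 0.627 to 29.0 ± 6.67 CPM (3.34 ± 0.27) and Gdf3, a TGF-beta family gene, from 2.02 ± 0.786 to 21.9 ± 6.41 CPM (3.41 ± 0.33). Fbp1 (3.64 ± 0.40), AA465934 (5.90 ± 0.45), Eif5al3-ps (6.25 ± 0.39) and Rps15a-ps8 (5.33 ± 0.50) rose as in HSC. Among the list members, the carbonic anhydrase gene Car2 (2.095 ± 0.41; lost with only the preGM groups, adjusted p = 0.064) and Itga2b, an integrin gene of megakaryocytes (2.02 ± 0.39), rose, and the latter had 3.82 ± 0.363 CPM in WT and 15.4 ± 11.8 CPM in MLL-ENL preGM. The GM-CSF receptor gene Csf2ra fell from 19.1 ± 5.14 to 6.38 ± 0.833 CPM (-1.58 ± 0.26). In all, 579 genes rose and 482 fell by the edgeR test (1061 calls, 54.6% higher, 985 of them above 2-fold), and the groups did not overlap for 27.8% of genes, where chance gives 10%. Scaled by library size alone, 74.9% of the calls were increases, and with limma on log2(RPKM + 0.1) 68.4%, whereas a fit of only the preGM groups gave 342 higher and 411 lower (45.4% higher). Without WT preGM replicate 1 the number fell to 564 with 46.8% higher, without MLL-ENL preGM replicate 2 it was 1342 with 66.3% higher, and without both libraries that stood apart 1125 with 49.3% higher.

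**Figure D2:**
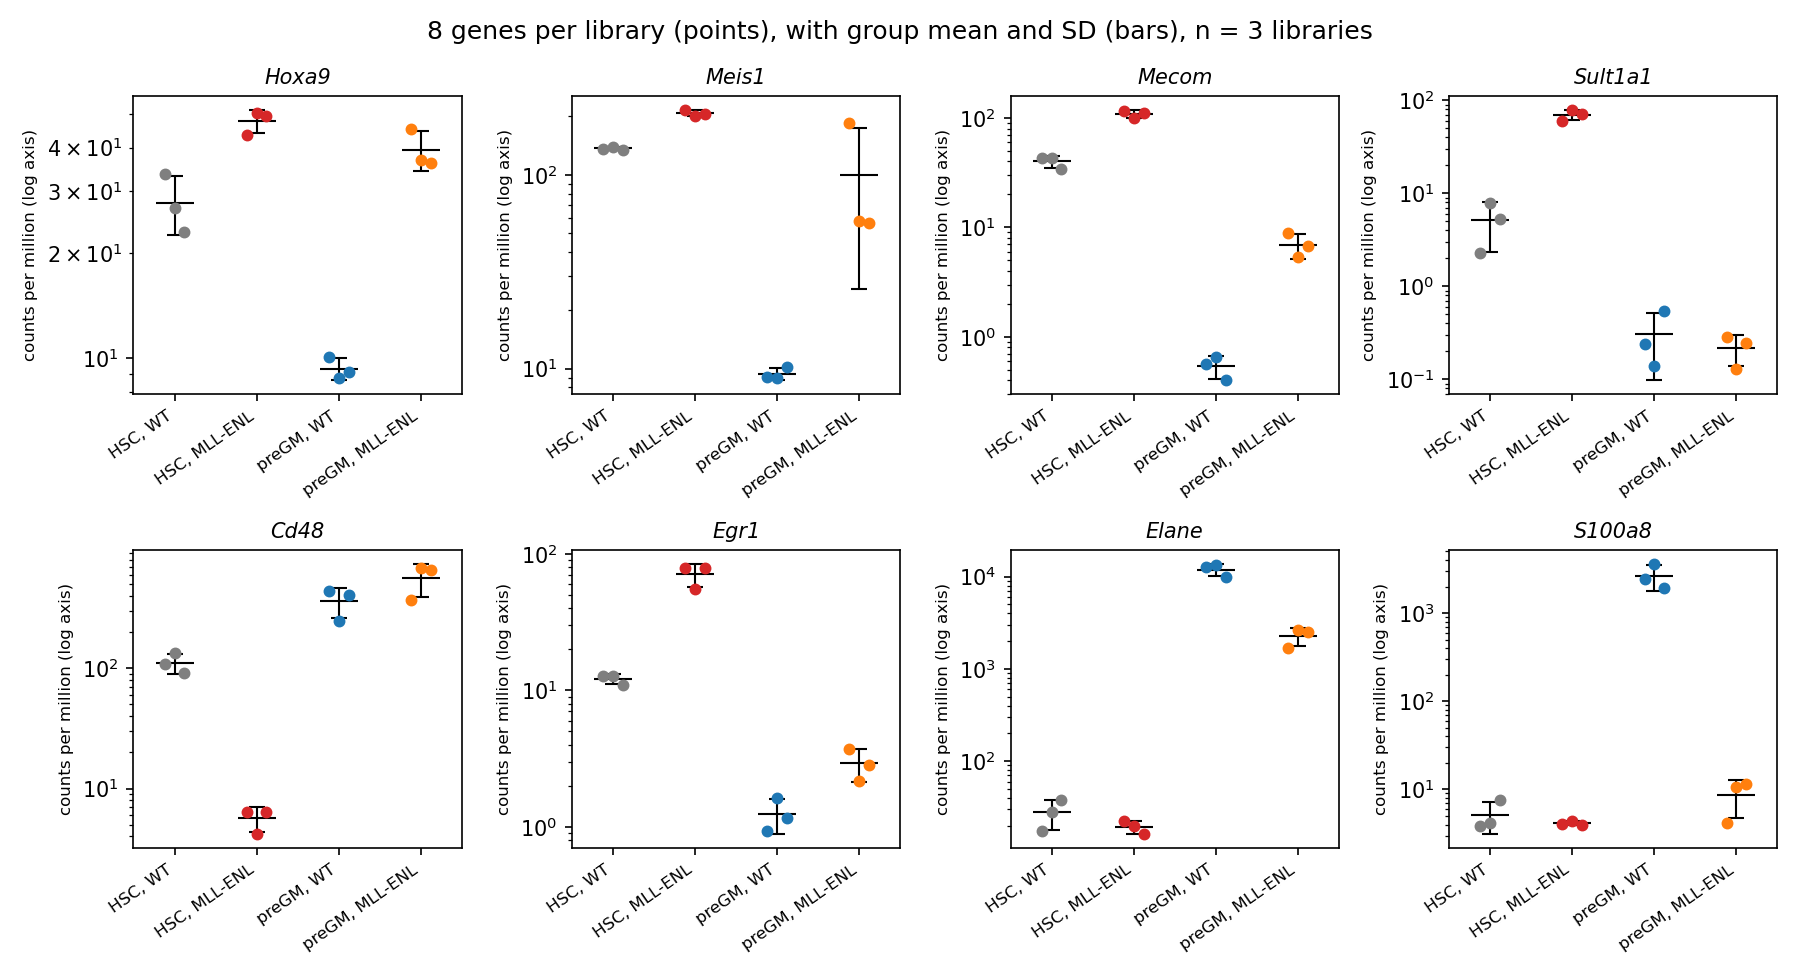
CPM after TMM scaling (log axis) of Hoxa9, Meis1, Mecom, Sult1a1, Cd48, Egr1, Elane and S100a8, with a point for each library of the 4 groups and a bar for the mean with its SD (n = 3). Sult1a1 and Egr1 are highest in MLL-ENL HSC (70.0 and 70.8 CPM), Cd48 is lowest there (5.67 CPM), and S100a8 is at 2665 CPM in WT preGM and 8.72 CPM in MLL-ENL preGM.

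Whether the response to MLL-ENL differed between preGM and HSC was tested with the interaction, which is positive where preGM responded more positively. Hoxa10, Meis1 and Mecom rose more in preGM, by 3.39 ± 0.44, 2.80 ± 0.52 and 2.25 ± 0.37 on the log2 scale (SE; adjusted p = 0.000425, 0.00611 and 0.00248). The Meis1 call was lost with limma (adjusted p = 0.0772 and 0.0661) and that of Mecom with limma on log2(RPKM + 1) (0.256). Flt3 fell in HSC and rose in preGM (3.18 ± 0.43, adjusted p = 0.000621). Cd48 fell in HSC and was not called in preGM, where it had 364 ± 103 and 565 ± 172 CPM (SD, n = 3; interaction 4.93 ± 0.47, adjusted p = 1.89e-05). Sult1a1 rose in HSC alone, with an interaction of -4.24 ± 0.70 (adjusted p = 0.00275). The Hoxa9 interaction was 1.30 ± 0.30 (adjusted p = 0.0244) and was lost without WT HSC replicate 1 or 2, MLL-ENL HSC replicate 1, 2 or 3, or WT preGM replicate 1 or 3 (adjusted p = 0.0792, 0.0532, 0.0874, 0.0675, 0.0655, 0.0569 and 0.0677). It was also lost with limma (0.317 and 0.321) and with library size alone (0.0587).

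MLL fusion target genes rose more in preGM than in HSC, with 8 of 21 positive and 0 negative (12 and 0 adjusted over the list alone; camera adjusted p = 3.48e-09, and adjusted p = 0.00818 with an estimated correlation). Stem cell genes had 8 of 25 positive and 3 negative (11 and 3 adjusted over the list alone; adjusted p = 0.00387, and adjusted p = 0.0789 with an estimated correlation), with Ly6a at -2.42 ± 0.34. Granulocyte and monocyte genes had 0 of 30 positive and 12 negative (1 and 18 adjusted over the list alone; adjusted p = 4.08e-12, and adjusted p = 0.00818 with an estimated correlation), with S100a9 at -8.21 ± 0.56 and Ltf at -9.63 ± 0.74. Mast cell, basophil and eosinophil genes had 1 of 11 positive and 3 negative (1 and 4 adjusted over the list alone; adjusted p = 0.0012, and adjusted p = 0.0374 with an estimated correlation). Of 12 immediate early and stress genes, 0 were positive and 4 negative (0 and 9 adjusted over the list alone; adjusted p = 2.11e-08, and adjusted p = 0.00413 with an estimated correlation), with Fos at -5.33 ± 0.75 and Junb at -2.47 ± 0.50. MYC and ribosome biogenesis genes had 1 of 17 positive, Cad, an enzyme gene of pyrimidine synthesis (1.36 ± 0.32), and 0 negative (6 and 0 adjusted over the list alone; adjusted p = 1.40e-05, and adjusted p = 0.00818 with an estimated correlation). Cad was lost without WT HSC replicate 2, MLL-ENL HSC replicate 1, 2 or 3, or WT preGM replicate 1 or 3 (adjusted p = 0.0868, 0.0795, 0.0726, 0.0842, 0.082 and 0.0715), and with limma (0.142 and 0.120). BCL2 family genes had 0 of 14 positive and 3 negative (1 and 5 adjusted over the list alone; adjusted p = 0.00333, and adjusted p = 0.0326 with an estimated correlation). Of 19 p53 target genes 0 were positive and 3 negative (0 and 6 adjusted over the list alone; adjusted p = 0.00215, and adjusted p = 0.0789 with an estimated correlation), with Btg2 at -1.94 ± 0.31. Of 27 proliferation genes 0 passed by the edgeR test in either direction (1 and 0 adjusted over the list alone), and 8 were positive at an unadjusted p under 0.05 (DESeq2 called 3, limma 0), while the list was shifted towards preGM by camera (adjusted p = 1.00e-04, and adjusted p = 0.0789 with an estimated correlation).

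The other 7 lists did not pass in the interaction, with camera adjusted p from 0.210 to 0.838. They were the MLL and elongation complex, megakaryocyte and erythroid, lymphoid, cell cycle inhibitor, interferon response, cytokine receptor and stromal lists. Dntt, absent from MLL-ENL HSC, went from 0.145 ± 0.0866 to 3.85 ± 1.58 CPM in preGM (4.76 ± 0.62). The interaction was positive for 168 genes and negative for 323 by the edgeR test. Of the 491, 27 rose in HSC and fell in preGM, 12 fell in HSC and rose in preGM, 7 rose in both and 1 fell in both. In preGM alone, 100 rose and 160 fell, in HSC alone 109 rose and 26 fell, and 49 were called in neither. The number was 309 without MLL-ENL HSC replicate 2, 298 without WT preGM replicate 1 and 1926 (55.2% positive against 34.2%) without both libraries that stood apart. With limma on log2(RPKM + 1) 20.1% were positive.

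How far the responses of HSC and preGM coincided was described by their overlap. Mecom, Pbx3, Fbp1, AA465934, Egr1 and Procr were among 92 genes that rose in both, where independent lists of these sizes would share 18.5. Pf4 and Plac8 were among 23 that fell in both, where independent lists would share 4.49. Another 27 genes rose in HSC and fell in preGM (15.4 for independent lists) and 12, Flt3 among them, fell in HSC and rose in preGM (5.40). Egr1 rose in both, although its preGM call was lost without WT preGM replicate 1 or 3 (adjusted p = 0.0887 and 0.0534). These comparisons share no library, but both come from 1 fit with shared dispersion estimates, so their calls are not independent. Leaving out MLL-ENL preGM replicate 1 alone took the HSC calls from 646 to 1281. The numbers for independent lists are therefore only a rough guide, and the overlaps in opposite directions exceeded them too. Across all 15662 genes the log2 changes correlated with Pearson r = 0.143 and Spearman rho = 0.232, and across the 154 genes called in both with r = 0.475 and rho = 0.421, genes not being independent replicates. The 115 genes called in the same direction became 75 without MLL-ENL HSC replicate 1, 75 without MLL-ENL HSC replicate 3 and 71 without WT preGM replicate 1. The correlation was 0.0888 without MLL-ENL preGM replicate 1.

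**Figure D3:**
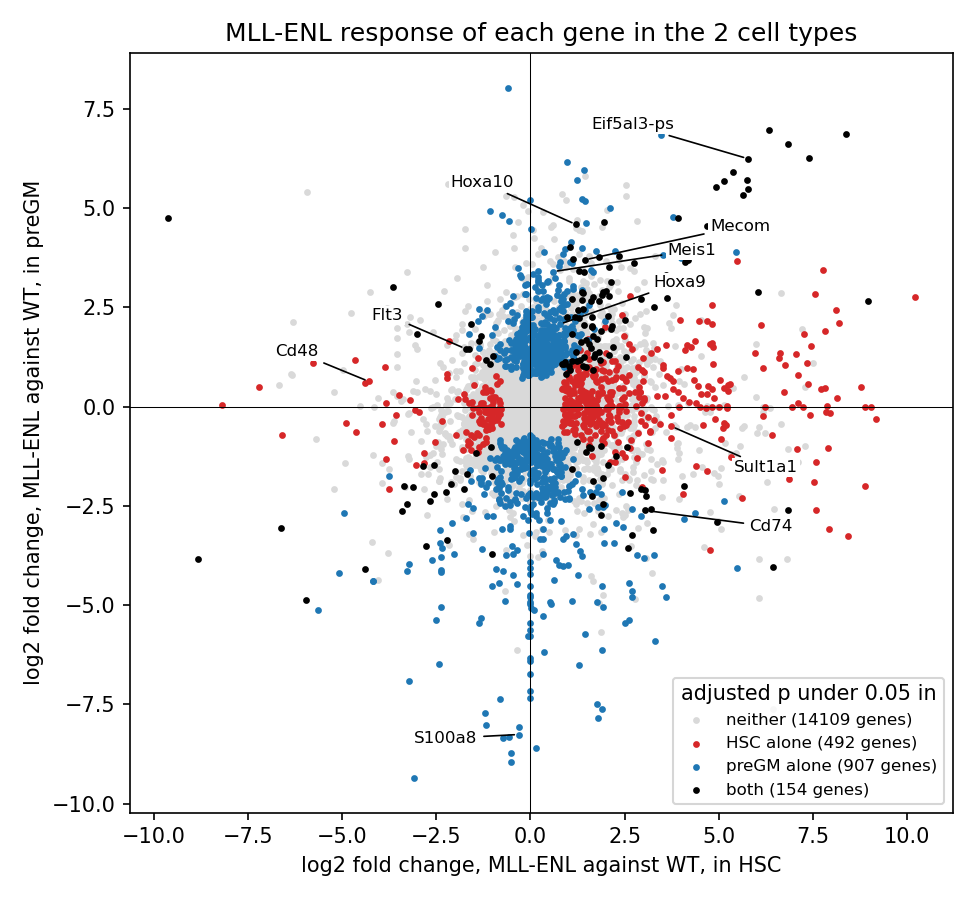
Log2 fold change with MLL-ENL in HSC (horizontal axis) against that in preGM (vertical axis), with a point for each of the 15662 genes tested, coloured by the comparison in which it was called. Of these, 492 were called in HSC alone, 907 in preGM alone and 154 in both, and Flt3, Cd74, Hoxa10 and S100a8 are among the labelled genes.

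The difference between the cell types without the fusion was measured by comparing preGM with HSC in WT. WT preGM had far less RNA of stem cell genes such as Esam, an endothelial adhesion molecule gene (84.4 ± 1.25 against 0.561 ± 0.173 CPM, SD, n = 3; -7.19 ± 0.33 SE) and Hlf, a stem cell transcription factor gene (157 ± 11.03 against 5.00 ± 0.765 CPM; -4.97 ± 0.25). They had far more of the granulocyte genes Elane (8.73 ± 0.46), S100a9 (8.94 ± 0.47) and Ngp (8.74 ± 0.46). Hoxa9 (-1.57 ± 0.22, adjusted p = 4.39e-05), Meis1 (-3.86 ± 0.40, adjusted p = 2.19e-06), Mecom (-6.23 ± 0.31) and Kmt2a (-1.76 ± 0.23, adjusted p = 2.22e-05) were lower in preGM. Mllt1 was lower too (-0.71 ± 0.22, adjusted p = 0.0177), a call lost without WT HSC replicate 1 or 3 or WT preGM replicate 1 or 3 (adjusted p = 0.0561, 0.0771, 0.0577 and 0.0744), and without a filter (0.0525). The chymase gene Cma1 (15.9 ± 10.2 CPM in WT preGM) was at least 97.8-fold, and Sh2d1b1 (13.8 ± 1.39 CPM) at least 84.5-fold, higher in preGM than in WT HSC, where neither had a count.

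All 25 stem cell genes were lower in WT preGM (0 higher and 25 lower adjusted over the list alone; camera adjusted p = 3.36e-24, and adjusted p = 0.000663 with an estimated correlation), and 16 of 21 MLL fusion target genes were lower and 1 higher (1 and 16 adjusted over the list alone; adjusted p = 1.87e-07, and adjusted p = 0.0134 with an estimated correlation). Granulocyte and monocyte genes were higher in 28 of 30 cases and lower in 0 (adjusted p = 3.36e-24, and adjusted p = 0.00172 with an estimated correlation), and mast cell, basophil and eosinophil genes in 10 of 11 with 0 lower (adjusted p = 1.98e-08, and adjusted p = 0.00407 with an estimated correlation). Interferon response genes were lower in 14 of 18 cases and higher in 1, for example Rtp4 (-4.96 ± 0.40) and Oasl2 (-4.94 ± 0.49; list adjusted p = 3.84e-05, and adjusted p = 0.00588 with an estimated correlation). BCL2 family genes were higher in 8 of 14 cases and lower in 1 (adjusted p = 0.00265, and adjusted p = 0.0216 with an estimated correlation). MYC and ribosome biogenesis genes were higher in 7 of 17 cases and lower in 0 (adjusted p = 0.00685, and adjusted p = 0.0290 with an estimated correlation), with Srm at 1.67 ± 0.31, but their median log2 difference of 0.58 became -0.10 with library size alone and -0.08 with limma on RPKM. Adjusted over the list alone, these 5 lists had 28, 10, 1, 8 and 8 members higher and 0, 1, 14, 1 and 0 lower.

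The remaining 9 lists did not pass between the WT cell types, with camera adjusted p from 0.0902 to 0.780. Without WT preGM replicate 2, the MLL and elongation complex and the proliferation lists passed (adjusted p = 0.0264 and 0.0183; 0.0261 for each without both libraries that stood apart), and without WT HSC replicate 3 the stromal list did (adjusted p = 0.0101). Proliferation genes were higher in 7 of 27 cases and lower in 0, but in 2 and 6 with library size alone and in 0 and 4 with each limma setting on RPKM, where the median log2 difference of 0.30 became -0.40 and -0.29. Aurka, a mitotic kinase gene (1.96 ± 0.37), and Rrm2, a ribonucleotide reductase gene (2.02 ± 0.39), were among the 7, and both were lost with limma (adjusted p = 0.0927 to 0.118). In total 2882 genes were higher and 3144 lower in WT preGM (47.8% of 6026 higher), and the groups did not overlap for 48.4% of genes, where chance gives 10%. Library size alone, which moved the median of all genes by -0.70, gave 16.2% higher, and limma on RPKM 20.6% and 20.7%. The number called ranged from 4563 to 7093 when single libraries were left out.

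With MLL-ENL, the same comparison asked how preGM and HSC differed after induction. Hoxa9 had 47.6 ± 3.66 CPM in HSC and 39.4 ± 5.14 CPM in preGM (-0.27 ± 0.21 SE, adjusted p = 0.321), and passed with library size alone (-0.82, adjusted p = 0.0198). Meis1 was lower in preGM (-1.06 ± 0.36, adjusted p = 0.0271), but not without MLL-ENL HSC replicate 1, 2 or 3 or MLL-ENL preGM replicate 2 or 3 (adjusted p = 0.071, 0.0597, 0.0641, 0.11 and 0.121) or with the longest transcript (0.841) or only the MLL-ENL groups (0.0743). Kmt2a was lower (-1.45 ± 0.23, adjusted p = 0.000136) and Mllt1 was not called (0.09 ± 0.22, adjusted p = 0.764). Mecom (-3.98 ± 0.26), Esam (-6.64 ± 0.31) and Egr1 (-4.59 ± 0.30) were lower in MLL-ENL preGM. Elane (6.88 ± 0.43), the cathepsin G gene Ctsg (7.64 ± 0.44) and the monocyte chemokine receptor gene Ccr2 (7.85 ± 0.49) were higher.

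Of 25 stem cell genes, 24 were lower and 0 higher in MLL-ENL preGM (camera adjusted p = 1.56e-21, and adjusted p = 0.000972 with an estimated correlation), and of 30 granulocyte and monocyte genes 21 were higher and 2 lower (adjusted p = 4.23e-10, and adjusted p = 0.0123 with an estimated correlation). Of 17 MYC and ribosome biogenesis genes, all 17 were higher, for example Npm1, the nucleophosmin gene (2.14 ± 0.33; list adjusted p = 9.86e-08, and adjusted p = 0.00242 with an estimated correlation). Of 27 proliferation genes, 18 were higher and 0 lower, among them Rrm2 (2.81 ± 0.40) and Ccnb1, a mitotic cyclin gene (2.05 ± 0.37; list adjusted p = 2.65e-06, and adjusted p = 0.0456 with an estimated correlation). Interferon response genes were lower in 14 of 18 cases and higher in 0 (adjusted p = 2.65e-06, and adjusted p = 0.00364 with an estimated correlation), and mast cell, basophil and eosinophil genes were higher in 9 of 11 and lower in 1 (adjusted p = 1.09e-05, and adjusted p = 0.0123 with an estimated correlation). Immediate early and stress genes were lower in 8 of 12 cases and higher in 0 (adjusted p = 0.0011, and adjusted p = 0.0166 with an estimated correlation). Adjusted over the list alone, these 7 lists had 0, 21, 17, 23, 0, 9 and 0 members higher and 25, 2, 0, 0, 14, 1 and 9 lower. All 4 tested stromal genes were lower (adjusted p = 0.0119, and adjusted p = 0.0470 with an estimated correlation), a call lost without MLL-ENL preGM replicate 1 (0.0732) or both libraries that stood apart (0.118).

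MLL fusion target genes were higher in 3 of 21 cases, Flt3 (2.53 ± 0.32) among them, and lower in 9 (3 and 10 adjusted over the list alone; adjusted p = 0.0462, and adjusted p = 0.244 with an estimated correlation). That call was lost without WT HSC replicate 1, 2 or 3, MLL-ENL HSC replicate 3, WT preGM replicate 3 or MLL-ENL preGM replicate 2 or 3 (adjusted p = 0.0556, 0.0593, 0.0566, 0.0881, 0.0538, 0.07 and 0.0677). Of 8 cell cycle inhibitor genes, 4 were lower and 0 higher (adjusted p = 0.0310, and adjusted p = 0.179 with an estimated correlation), with Cdkn1c, a CDK inhibitor gene expressed in quiescent stem cells, at -5.54 ± 0.42. This call was lost without MLL-ENL preGM replicate 1 (adjusted p = 0.0732) or both libraries that stood apart (0.0707). The other 6 lists did not pass, with camera adjusted p from 0.224 to 0.963, although the lymphoid list did without MLL-ENL HSC replicate 1 or 2 (adjusted p = 0.0375 and 0.0473). In total 3199 genes were higher and 3315 lower in MLL-ENL preGM (49.1% of 6514 higher), and the groups did not overlap for 54.8% of genes, where chance gives 10%. With library size alone 18.1% of the calls were higher, and with limma on RPKM 21.99% and 21.6%. The number called ranged from 5036 to 7205 when single libraries were left out.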

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

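The tests that set other explanations against the fall of the granulocyte genes were chosen only after that result was seen, and the counts over other splits of the libraries were planned. Values below, where no cell type is named, are the response in preGM minus that in HSC on the log2 scale, from the edgeR interaction test, which picked them out because the cell types answered differently to MLL-ENL. The genes named here passed the test (adjusted p up to 0.0476).

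Among MLL target and stem cell genes, the interaction was positive for Hoxa10 (3.39), Flt3 (3.18), Meis1 (2.80), Mecom (2.25), Hoxa7 (2.24) and Hoxa9 (1.30), and negative for Sult1a1 (-4.24), Ly6a (-2.42) and Mllt3 (-1.33). The lists gave camera adjusted p = 3.48e-09 for MLL fusion targets, and adjusted p = 0.00818 with an estimated correlation. For stem cell genes they gave adjusted p = 0.00387, a call lost at adjusted p = 0.0789 with an estimated correlation. Mllt3, a fusion partner of MLL, had 63.7 ± 7.48 and 119 ± 6.02 CPM in WT and MLL-ENL HSC (SD, n = 3) and 10.7 ± 2.43 and 7.95 ± 0.442 CPM in preGM. Its interaction was lost without WT HSC replicate 2 or 3 (adjusted p = 0.0575 and 0.0688), any MLL-ENL HSC library (0.0577 to 0.0769), WT preGM replicate 3 (0.0537) or MLL-ENL preGM replicate 3 (0.0695). The Hoxa9 interaction was lost without WT HSC replicate 1 or 2, any MLL-ENL HSC library or WT preGM replicate 1 or 3 (0.0532 to 0.0874). With library size alone, Mllt3 and Hoxa9 were lost (0.081 and 0.0587), and with limma Mllt3 (0.0749 and 0.0567), Hoxa9 (0.317 and 0.321), Meis1 (0.0772 and 0.0661) and, on log2(RPKM + 1), Mecom (0.256).

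Outside the lists, Ackr1, a chemokine-binding receptor gene (6.03), Cd48 (4.93), Tespa1 (4.85), the melanocortin receptor gene Mc5r (3.58) and Cd27 (3.51) were positive, and the acute phase gene Saa3 (-9.21) and Ly6i (-8.01) were negative. Tespa1 had 13.5 ± 7.01 and 1.67 ± 0.181 CPM in WT and MLL-ENL HSC, and 14.3 ± 3.40 and 51.4 ± 0.600 CPM in preGM (SD, n = 3). Saa3 had 133 ± 201 CPM in WT preGM, and its call was lost without any WT HSC library (adjusted p = 0.0803 to 0.117), MLL-ENL HSC replicate 2 (0.445), WT preGM replicate 2 (0.0748) or any MLL-ENL preGM library (0.0673 to 0.132). It was also lost with library size alone (0.0508), no filter (0.189), the stricter filter (0.0812) and limma (0.183 and 0.117), and Ackr1 with limma on log2(RPKM + 1) (0.166).

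Markers of other cell types that differed were Mfsd2b (3.09) and Itga2b (2.16) of the megakaryocyte and erythroid list, Prss34 (-6.55), Mcpt8 (-3.42), Cpa3 (-3.005) and Fcer1a (2.82) of the mast cell list (camera adjusted p = 0.0012), and Dntt. The fitted interaction of Dntt (14.39) depends on the prior count, since MLL-ENL HSC had no counts, and is no measure of size. Itga2b was lost without any WT HSC, MLL-ENL HSC or WT preGM library (adjusted p = 0.0528 to 0.110), and Cpa3 without WT HSC replicate 2 (0.0522) or MLL-ENL HSC replicate 1 (0.0556). With limma both were lost (0.137 and 0.126 for Itga2b, 0.115 and 0.062 for Cpa3), and with library size alone Itga2b (0.0863).

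Genes of growth, stress and survival that differed were Fos (-5.33), Junb (-2.47), Trib3 (-2.41) and Zfp36 (-1.63) of the immediate early list (camera adjusted p = 2.11e-08), and Fas (-2.44), Btg2 (-1.94) and Bax (-1.63) of the p53 list (adjusted p = 0.00215, a call lost at adjusted p = 0.0789 with an estimated correlation). Bcl2a1b (-5.40) and Bak1 (-2.22) stood in the BCL2 family list (0.00333), Rb1 (-1.18) among the cell cycle inhibitors, Cad (1.36) in the MYC list (1.40e-05) and Csf2ra (-1.96) among the cytokine receptors. The proliferation list gave adjusted p = 1.00e-04, a call lost at adjusted p = 0.0789 with an estimated correlation, and 0 of its 27 members passed the edgeR test (8 were positive at an unadjusted p under 0.05, 3 with DESeq2 and 0 with limma). Trib3 was lost without MLL-ENL HSC replicate 2 or 3, WT preGM replicate 1 or 3, or MLL-ENL preGM replicate 2 or 3 (adjusted p = 0.115, 0.0791, 0.0903, 0.0981, 0.071 and 0.0796). Bax was lost without WT HSC replicate 1 or 2, any MLL-ENL HSC library or WT preGM replicate 1 (0.0502 to 0.0745). Fas was lost without WT HSC replicate 1 or 3, MLL-ENL HSC replicate 1 or 2, WT preGM replicate 1 or 3, or MLL-ENL preGM replicate 1 or 2 (0.0502 to 0.0964). Bcl2a1b, with 49% of its exon bases shared with another gene, was lost without MLL-ENL HSC replicate 1 or 3 or WT preGM replicate 2 (0.0518, 0.0655 and 0.0545). Rb1 was lost without any library but MLL-ENL preGM replicate 1 (0.0503 to 0.136), Zfp36 without any library but WT preGM replicate 2 or MLL-ENL preGM replicate 1 (0.0597 to 0.122), and Cad without WT HSC replicate 2, any MLL-ENL HSC library or WT preGM replicate 1 or 3 (0.0715 to 0.0868). With library size alone, Trib3, Fas, Rb1 and Zfp36 were lost (0.0751 to 0.148), and with both limma settings these and Cad and Bak1 (0.0591 to 0.348). Rb1 was also lost with no filter (0.0871) and the longest transcript (0.316).

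The fall of granulocyte and monocyte genes in MLL-ENL preGM was among the largest differences between the cell types, with Ltf at -9.63, Camp at -8.76, S100a9 at -8.21, S100a8 at -7.94 and Ngp at -7.61 (list adjusted p = 4.08e-12). Scaling and the libraries that stood apart were excluded as its whole cause, since 18 of the 19 members that fell were still called lower with library size alone, and 18 without both of these libraries. In lists written after these falls had been seen, 10 of 10 genes of secondary granules and S100 proteins, made late in maturation, fell in preGM (median log2 change in preGM -8.14), against 5 of 6 genes of primary granules, made earlier (-1.74). The gap between these preGM medians (-6.40) therefore describes genes already seen to fall and tests no explanation. Fewer maturing granulocytes in the MLL-ENL cultures, a candidate explanation, cannot be told apart from lower expression per cell, because bulk RNA gives no number of cells and the granule lists were not independent of the result.

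In HSC the primary granule genes had a median log2 change of -0.55 (camera p = 0.0038 with the preset and p = 0.123 with an estimated correlation) and the secondary granule genes one of -0.41 (p = 0.508 and p = 0.633). In the interaction the secondary granule genes had a median of -7.68, with 8 of 10 negative, and the primary granule genes -1.17, with 1 of 6 negative. Of the primary granule genes, 6 of 6 had at least 1 CPM in each group and 6 were members of the fixed granulocyte list, and of the 10 secondary granule genes 6 were members of it. At least 1 CPM was reached in WT HSC, MLL-ENL HSC, WT preGM and MLL-ENL preGM by 3, 3, 10 and 5 of the secondary granule genes, so that their HSC and interaction medians rest in part on genes near the floor in HSC. The lineage markers of both gates would remove mature granulocytes before the culture, not those formed during it.

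A signal in exons outside the comparisons concerned the fusion partner genes. Exons 2 to 11 of Mllt1 (chromosome 17, 56894667 to 56927172, the exons before the last) had 42, 23 and 28 counts in the MLL-ENL HSC libraries, a mean of 31.0, against 0, 1 and 0 in WT HSC (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allow). In preGM they had 54, 17 and 18 counts with MLL-ENL and 10, 25 and 13 without (exact p = 0.5). The last exon, 12, had 368, 404 and 420 counts in MLL-ENL HSC and 401, 390 and 385 in WT HSC (exact p = 0.8), and 729, 502 and 605 in MLL-ENL preGM against 425, 276 and 406 in WT preGM (exact p = 0.1). Exons 1 and 2 of Kmt2a had 21, 22 and 15 counts in MLL-ENL HSC and 0, 7 and 0 in WT HSC, and its last exon, 36, had 1771, 1471 and 1391 against 737, 988 and 696 (exact p = 0.1 for each). In preGM the first exons of Kmt2a had 4, 12 and 10 counts with MLL-ENL and 0, 5 and 2 without (exact p = 0.2), and the last exon 1245, 547 and 658 against 351, 326 and 386 (exact p = 0.1). These counts are not adjusted for depth, whose group mean was higher with MLL-ENL in HSC and in preGM.

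For the interaction, 50 splits of the libraries were drawn, the real one included. The real split gave 491 genes and the highest other 129, so that 1 split of 50 was as large. Labels of WT and MLL-ENL were moved within each cell type. The splits thus stand for no genotype difference at all, not for equal responses, and cannot exclude chance for the interaction. For the other comparisons the 10 splits of 6 libraries are too few for a share under 0.05. Their real values and highest other splits were 646 and 0 genes in HSC, 1061 and 0 in preGM, 6026 and 0 in WT, and 6514 and 0 with MLL-ENL, and in each 1 split was as large as the real one.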

How the results depend on the processing

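Tests chosen only after the result was seen were the settings with the longest transcript, without mitochondrial and ribosomal-RNA-like features, and without both libraries that stood apart (WT preGM replicate 2 and MLL-ENL preGM replicate 1). The numbers of genes called between the cell types stayed within 1.5 times in every setting run, 4563 to 8034 in WT and 5036 to 8142 with MLL-ENL. In HSC, DESeq2 called 1338 genes (881 higher, 457 lower) in place of 646, limma on log2(RPKM + 1) 1017, a fit of only the HSC groups 2503 and the fit without both libraries 3362, while leaving out single libraries gave 312 to 1281. In preGM, DESeq2 called 1734 in place of 1061, limma 684 on log2(RPKM + 0.1) and 571 on log2(RPKM + 1), and leaving out single libraries gave 564 to 1342. The interaction gave 1055 with DESeq2 in place of 491, 299 with limma on log2(RPKM + 0.1), 1926 without both libraries, and 298 to 694 with single libraries left out. Genes called the same way in both cell types numbered 217 with DESeq2 and 267 without both libraries in place of 115, and 71 to 138 with single libraries left out. The correlation of the responses, 0.143, became 0.0808 without a filter, 0.224 with the stricter filter, 0.212 and 0.234 with limma on log2(RPKM + 0.1) and log2(RPKM + 1), 0.238 with only the groups compared, 0.0833 without both libraries and 0.198 over the genes called in at least 1 comparison, and lay from 0.0888 to 0.151 with single libraries left out. For most of these differences the cause was not tested, but fewer libraries in a fit cannot alone account for the rise in HSC. Leaving out WT preGM replicate 2 or MLL-ENL preGM replicate 1 raised the HSC calls to 972 and 1281. Leaving out any other preGM library lowered them to between 483 and 588. The preGM libraries do not enter the HSC group means. Without both libraries that stood apart, HSC log2 changes shifted by a median of -0.000654, while the share of increases fell from 77.4% to 48.1%. The added HSC calls and this share therefore follow the dispersion estimates that all groups share, not altered HSC levels. Without both libraries, 644 of the 646 genes called in HSC, 695 of the 1061 in preGM and 476 of the 491 of the interaction were called again.

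Of 80 list tests, 42 passed, 28 with an estimated correlation, 37 without both libraries and 36 to 43 with single libraries left out. In 9 of the 80, none of them past the threshold, the median, the mean and the test differed in sign. Of the called named genes over all settings, 1 changed sign: Klrb1c, at -4.68 in the WT comparison, was at 1.87 without WT HSC replicate 1, with adjusted p = 0.546, the highest over its settings, and lay between -6.50 and 1.87 with single libraries left out. Calls of named genes were lost in 98, 111, 131, 47 and 33 gene settings of HSC, preGM, the interaction, WT and MLL-ENL, gained in 108, 48, 59, 17 and 3, and kept on their side of the threshold with the same sign in 1964, 1888, 1635, 1760 and 1666, while the sign changed without a call in 10, 7, 6, 0 and 7. Scaling by library size alone moved the median of all genes by 0.19 in HSC, 0.32 in preGM, 0.13 in the interaction, -0.70 in WT and -0.56 with MLL-ENL. Few changes of 2-fold were recovered in the simulation, 4.12% in HSC and 5.05% in preGM. These rates do not give the reach of the real comparisons. The simulation changed fewer genes than were called in HSC or preGM, which makes the adjusted p-values stricter. In the WT comparison, 4843 of the 6026 genes called exceeded 2-fold, so smaller changes were called as well.

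No pairing of the samples by replicate number was detected. Deviations from the group means correlated at -0.105 to 0.101 between same-numbered libraries, and the own number was best in 2 of 18 cases. Low correlations cannot show that same-numbered libraries were handled separately. With the number as a replicate block, 501 genes were called in HSC, 863 in preGM, 403 in the interaction, 5524 in WT and 6012 with MLL-ENL, 102 genes the same way in both cell types, and the correlation was 0.144. Of the list tests 41 passed, and the block ended the MLL fusion target call with MLL-ENL (adjusted p = 0.0577, the range over single libraries left out being given in the results).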

Other observations

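The tests of major histocompatibility complex (MHC) class II genes and of genes near Col1a1 in this part were chosen only after the results were seen. In HSC, the haem oxygenase gene Hmox1 rose with MLL-ENL from 0.935 ± 0.754 to 9.73 ± 5.06 CPM (SD, n = 3; log2 change 3.42, adjusted p = 0.00498), and Lrmda (-2.77) and the T cell receptor gamma gene Tcrg-C1 (-3.05) fell. In preGM, Adgrl4, an endothelial adhesion receptor gene, rose from 9.17 ± 1.78 to 78.3 ± 36.2 CPM (3.10) and Tmem98 from 3.39 ± 2.12 to 26.0 ± 3.93 CPM (2.91). These levels lay below those of WT HSC, where Adgrl4 had 154 ± 13.7 and Tmem98 59.0 ± 1.24 CPM. The ficolin gene Fcnb (-8.32) and the chitinase-like genes Chil3 (-8.02) and Chil1 (-8.06) fell in preGM, Chil3 from 129 ± 71.2 to 0.511 ± 0.285 CPM. The platelet chemokine gene Ppbp fell in HSC (-3.76, adjusted p = 0.0199), a call lost without WT HSC replicate 2 or MLL-ENL HSC replicate 1 or 3 (adjusted p = 0.0558, 0.0903 and 0.0878).

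Genes of MHC class II moved in opposite directions in the cell types. Cd74, the invariant chain gene (chromosome 18, 60803848 to 60812652), had 5.69 ± 1.07 CPM in WT HSC and 47.2 ± 12.8 CPM in MLL-ENL HSC (log2 change 3.05), and 261 ± 152 and 42.6 ± 15.3 CPM in preGM (-2.61; interaction -5.66). H2-Aa changed by 3.25 and -3.10, H2-Ab1 by 1.55 and -1.03 and H2-Eb1 by 2.70 and -3.23. H2-Aa was given by the naming rule in HSC, and the others were chosen after their values were seen. All 4 genes rose in HSC, fell in preGM and differed in the interaction by the edgeR test. The call of H2-Eb1 in HSC was lost without WT HSC replicate 1 or MLL-ENL HSC replicate 1, 2 or 3 (adjusted p = 0.0823, 0.061, 0.0568 and 0.0643), and with no filter (0.0538). Its call in preGM was lost with limma on log2(RPKM + 0.1) (0.0591). That of H2-Ab1 in preGM was lost without WT preGM replicate 1, 2 or 3 or MLL-ENL preGM replicate 1 or 3 (0.0535, 0.0535, 0.112, 0.0744 and 0.0531) and with only the preGM groups (0.126). With library size alone it was -0.77 (0.0854), and with limma -0.66 and -0.65 (0.158 and 0.169).

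In preGM the libraries that stood apart were excluded as the whole source of the falls of Cd74, H2-Aa and H2-Eb1. Without both, these changed by -2.79, -2.85 and -3.24 (edgeR adjusted p up to 0.0107). H2-Ab1 was at -0.85 (adjusted p = 0.0389), but was lost without either library alone. Neither library is from HSC, so leaving them out does not test the rise in HSC. Dendritic cells or macrophages in the WT preGM cultures are a candidate source of the difference in preGM, since 16 other genes of these cells were shifted downwards with MLL-ENL (camera p = 0.00719 with an estimated correlation) and 4 of them fell (Cst3, Ifi30, Cd209a and Mpeg1). For the rise in HSC, the same 16 genes had a median log2 change of 0.79 (camera, limma, p = 0.208 with an estimated correlation), and such cells in the MLL-ENL HSC cultures cannot be told apart from expression in the stem cells, because the members went both ways and many had under 1 CPM. Cst3, the most abundant, had 337, 384, 1282 and 400 CPM and Cd68 24.8, 32.4, 189 and 102 CPM in WT HSC, MLL-ENL HSC, WT preGM and MLL-ENL preGM. The lineage and Kit gates would remove such cells before the culture, not those formed in it.

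Of the 8 dendritic cell genes, 3 fell in preGM, and the list test gave 0.893 in HSC and 0.0136 in preGM (camera p with an estimated correlation; 0.885 and 0.00101 with the preset). Of 10 macrophage genes, 8 were tested and 1 fell in preGM, and the test gave 0.0717 and 0.0423 (0.0449 and 0.0197 with the preset correlation). At least 1 CPM was reached in WT HSC, MLL-ENL HSC, WT preGM and MLL-ENL preGM by 3, 4, 5 and 3 of the dendritic cell genes and by 3, 4, 7 and 8 of the macrophage genes, of which 1 was also in a fixed list.

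In the main fit, genes called the same way in both cell types lay near Col1a1 more often than other genes. Of 115 such genes, 14 lay within 25 Mb of it on chromosome 11, a window with 755 of the 15662 tested genes (odds ratio 2.77, 95% interval 1.45 to 4.89, Fisher's exact p = 0.00126), and 0 of 325 such windows on other chromosomes held as many genes (at most 8), though 26 had as high a share. Genes called in 1 cell type were not enriched there (Fisher's exact p = 0.896, odds ratio 0.975). For the genes called the same way in both, the exact p without the Hoxb genes was 0.0115 (12 of 113). Fisher's test takes genes as independent, but some of the 14 are overlapping neighbours, such as Hoxb5 and Hoxb5os, in counts without strand. With as high a share in 26 other windows too, the enrichment is not established, and these tests exclude no explanation. DNA of another strain carried along with the transgene may be the source of any enrichment. It cannot be told apart from MLL-ENL itself, because the fusion and the strain go together in the design and counts show no variants. Fisher's p lay between 0.000157 and 0.0375 with single libraries left out, but was 0.147 without both libraries that stood apart and 0.238 with limma on log2(RPKM + 1).

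The genes of that window, all 14 of them higher with MLL-ENL, included AA465934 (log2 change 5.37 in HSC and 5.90 in preGM; chromosome 11, 83291699 to 83294632), Elobl (6.32 and 6.97), Rapgefl1 (4.78 and 3.92) and Cuedc1 (1.81 and 2.67), the last 3 chosen after their values were seen.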
